A study of Homo sapiens with 6 samples.

How the data were processed

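RNA sequencing was compared between 3 libraries of A549 cells labelled scramble and 3 libraries labelled shILF2, taken from the sample titles. A549 is an established human lung adenocarcinoma line. Per the labels' protocols, ILF2 was knocked down by lentivirus and the libraries were prepared with oligo-dT beads, which select polyadenylated RNA. The labels do not give the hairpin sequence or the number of hairpins, and a characteristic of the scramble libraries calls those cells wild, while their titles say scramble; the titles were used.

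Per the submitters' processing notes, HISAT2, Bowtie2 and RSEM were used with the hg19 genome build; their versions and the role of each aligner are not given in the sources used here. Each deposited table held 1 library, with a row per gene. Per the file headers, the authors gave an expected count for each gene, which RSEM estimates by dividing reads that match several genes or transcripts between them, and which need not be a whole number. The authors also gave FPKM values, per the file headers, which divide by gene length and by library size. A further deposited column, headed as a length, differed between libraries for many genes and was read as a gene's transcript length in bases weighted by transcript abundance, as RSEM computes it; the headers do not define it. The tables listed only genes with a value above 0, the lowest expected count being 0.16, so a gene missing from a library was set to 0. Of 19667 genes listed in any library, 15906 were listed in all 6, and 1799 had identifiers that begin with BGI_novel and no gene name. Of the other 17868 genes, 17526 had their identifier in the reference gene table. Between 72.0% and 73.2% of the expected counts in a library were whole numbers, to within 0.005. Strand was not stated, so overlapping and antisense genes cannot be told apart here.

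Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries were scaled by TMM, and shILF2 was tested against scramble with the quasi-likelihood F-test (robust fit). The p-values were adjusted by the Benjamini-Hochberg method over the 15587 genes tested, with a threshold of 0.05. Normalised levels are CPM, counts scaled by the TMM-adjusted library size, given as mean ± SD over 3 libraries. Log2 fold changes are given ± standard error (SE). The depth was 32738977 to 35381986 expected counts per library, and the biological coefficient of variation was 0.186. The 6 libraries were compared pairwise by chi-square over genes, and replicates of the same group differed by 12.2 to 57.5 per gene, well above sampling noise, so none was treated as a duplicate.

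A total of 27 gene lists were tested with camera (limma 3.58.1) against all other genes tested, with a preset correlation of 0.01, Benjamini-Hochberg adjustment over the lists, and repeats with an estimated correlation and with fry. The lists covered ILF2 partners, p53 targets, E2F and DNA replication, mitosis, homologous recombination and Fanconi genes, interferon response, inflammatory cytokines and NF-kB, oxidative phosphorylation, mitochondrial dynamics and mitophagy, glycolysis and hypoxia, NRF2 targets, the unfolded protein response and ATF4, cholesterol synthesis, ribosomal proteins, ribosome biogenesis, splicing factors, TGF-beta targets and mesenchymal genes, epithelial junctions and keratins, lysosome and autophagy, apoptosis regulators, immediate early genes and replication-dependent histones. They also covered markers of immune cells, fibroblasts, endothelium, alveolar and club cells, and neuroendocrine cells. Annotation terms carried by the deposited tables were tested per direction with a one-sided Fisher's exact test, for 1562 terms with 15 to 300 tested members each, which made 3124 tests adjusted together, against the genes tested as background.

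The groups, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule the text names ILF2, the 12 largest rises and the 12 largest falls among genes past the threshold, with at least 10 CPM in the higher group and no overlap between groups. It also names up to 4 members past the threshold of each list that camera called, and the 2 most abundant members of each list of cell type markers. Some genes that the rule names are not reported here. Genes named outside this rule are said to be so. The alternatives were DESeq2 size factors, no scaling beyond total counts, no filter, a filter at 1 CPM, the replicate number as a replicate block, leaving out each library, DESeq2 1.42.0, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with and without a filter at 0.5 FPKM in 3 libraries, an absolute log2 fold change of at least 1, and an adjusted p threshold of 0.01. Alternatives added after the data were seen were a test of genes with whole counts only, a background of annotated genes for the terms, and a correction for GC content.

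The GC correction used the median GC content of a gene's transcripts in GENCODE release 29, matched on gene identifiers, for sequence composition only and with no coordinates. It covered 13863 of the genes tested (88.9%) and 94.6% of the genes called. In each library the deviation of log2 CPM from the mean of the 6 libraries was smoothed over GC content (lowess, span 0.3) and entered the fit as an offset.

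The gene test was tested on counts simulated from the real means and library sizes with 200 changed genes among 15313. It recovered 44.8% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 90.9% of those changed 4-fold, and 8.3% of its calls were false. In simulated lists of 40 genes, camera called the lowered list and 0 of 20 unchanged ones, and the term test called 0 terms on random genes. The simulated genes varied independently of each other. The simulation therefore could not show false calls of real lists whose members move together between libraries. With a GC trend planted in 1 library, the corrected test recovered 99.5% of 200 genes changed 2-fold among 13742, and 20 of its 219 calls were false. The uncorrected test recovered 99% of them, with 15 of its 213 calls false. These changed genes were all raised, had a higher minimum abundance, and took dispersions from the corrected fit (biological coefficient of variation 0.126 against 0.186). Their recovery therefore cannot be set against the 76.1% above, and the real trends were not limited to 1 library. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the figures.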

Results

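The experiment asked which genes ILF2 regulates in A549 cells, a lung adenocarcinoma line. ILF2 encodes a nuclear protein that binds RNA as part of protein complexes. RNA sequencing covered 3 libraries of cells labelled scramble and 3 libraries of cells with a short hairpin RNA against ILF2 (shILF2). The scramble libraries held 35381986, 34769620 and 34266871 expected counts for replicates 1 to 3, and the shILF2 libraries 34827531, 32738977 and 34776904. Each library listed 17528 to 17771 genes. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

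ILF2 transcript fell in all 3 shILF2 libraries. Its level was 185 ± 17.9 CPM in scramble (SD, n = 3) and 33.1 ± 1.71 CPM in shILF2 (SD, n = 3), which is 17.9% of the scramble mean. Single libraries held 202, 186 and 166 CPM in scramble against 32.6, 31.7 and 34.99 CPM in shILF2. The log2 fold change was -2.48 ± 0.11 (SE), with an adjusted p of 8.16e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg), and ran from -2.57 to -2.40 over 17 alternatives.

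**Figure D1:**
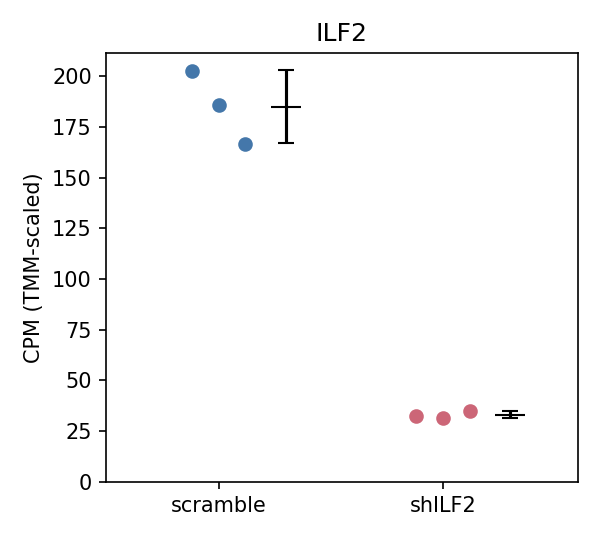
Normalised level (CPM, axis from 0) of ILF2 in each of the 6 libraries, as points by group, with the mean and SD of the 3 libraries beside them. ILF2 fell to 17.9% of its scramble mean with no overlap between groups.

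SYT1, a calcium sensor of vesicle release, rose from 3.71 ± 1.32 to 17.4 ± 4.53 CPM (SD, n = 3 each). FST, a secreted antagonist of activin, rose from 2.68 ± 0.869 to 12.2 ± 2.73 CPM, and CCL2, a monocyte chemokine, from 8.88 ± 0.434 to 26.0 ± 6.13 CPM. Among genes called with at least 10 CPM in the higher group, the fall was largest, after ILF2 and the genes with shared reads given below, for C6orf223 and for BMP2, a secreted morphogen, which went from 41.5 ± 5.63 to 11.6 ± 1.05 CPM. CEACAM6, a surface adhesion protein, fell from 466 ± 30.0 to 189 ± 3.89 CPM.

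In all, 371 of 15587 genes passed the test, 148 higher and 223 lower in shILF2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). An absolute log2 fold change of at least 1 was reached by 108 of them, 50 higher and 58 lower. All 371 had every library of a group above every library of the other, a separation seen in 21.4% of genes tested and given by chance in 10%. Genes picked by such a test nearly always separate in this way, so the separation lends the calls no further support. Among genes called with at least 10 CPM in the higher group, the other large rises were those of ANKRD1 (log2 fold change 1.53 ± 0.15), NPW (1.49 ± 0.23), NRCAM (1.46 ± 0.20), FRAS1 (1.44 ± 0.17), COL12A1 (1.39 ± 0.14), TMEM156 (1.35 ± 0.17), CA8 (1.29 ± 0.15) and KCNH1 (1.27 ± 0.21). For SYT1, FST and CCL2 the log2 fold changes were 2.23 ± 0.27, 2.18 ± 0.27 and 1.55 ± 0.17. ANKRD1 is a nuclear and muscle-associated ankyrin repeat protein, NRCAM a cell adhesion molecule, and FRAS1 and COL12A1 are extracellular matrix proteins. Adjusted p values of these 11 genes ran from 3.23e-04 to 0.00886 (edgeR).

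Further large falls were those of EDAR, a receptor of the TNF receptor family (-1.60 ± 0.15), COL8A1, a collagen chain (-1.41 ± 0.13), MUC16, a membrane mucin (-1.41 ± 0.15), C11orf86 (-1.36 ± 0.13) and FAM83A (-1.26 ± 0.11). For C6orf223, BMP2 and CEACAM6 the values were -2.03 ± 0.24, -1.84 ± 0.14 and -1.30 ± 0.10, and adjusted p values of these 8 genes ran from 1.31e-04 to 0.00122 (edgeR). The number of genes called changed when 1 library was left out. It was 183 without scramble replicate 2, 143 without shILF2 replicate 1, 86 without shILF2 replicate 2 and 1299 without scramble replicate 3 (702 higher and 597 lower). A fit with fewer libraries has less power, so a lower count or a lost call need not come from the library left out. The rise to 1299 goes against that loss of power. NRCAM lost its call without scramble replicate 1 (1.40, adjusted p = 0.0611) and KCNH1 without shILF2 replicate 2 (1.16, adjusted p = 0.0628, edgeR). Over 18 alternatives (edgeR, DESeq2 and limma), KCNH1 kept its call in 14 and NRCAM in 16. FRAS1, CA8, C6orf223 and MUC16 kept theirs in 17, with a highest adjusted p of 0.0843, 0.128, 0.0704 and 0.0510. DESeq2 called 950 genes, 364 of which were among the 371.

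**Figure D2:**
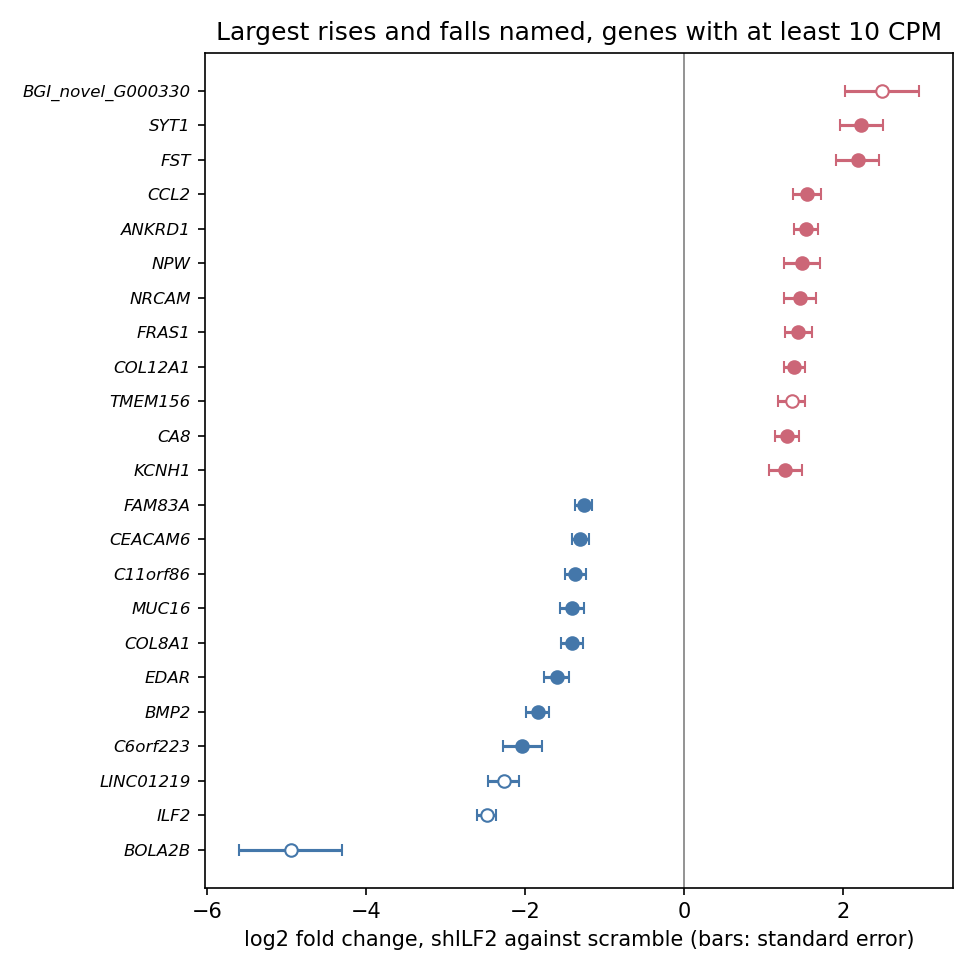
Log2 fold change, shILF2 against scramble, of the genes named for the largest rises (red) and falls (blue) among genes called with at least 10 CPM in the higher group, with bars for the standard error. Open circles mark genes with a fractional expected count in at least 1 library, which share reads with another gene; they include BOLA2B at -4.95 and ILF2 at -2.48.

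Among the largest changes, a further 3 belong to genes that had no whole expected count in any library. At least some of their reads were divided with other genes, to an extent that was not measured, and these changes are uncertain. BOLA2B, a near-identical copy of BOLA2, had a log2 fold change of -4.95 ± 0.64 (adjusted p = 0.0202, edgeR), from 18.3 ± 10.8 to 0.587 ± 0.196 CPM. LINC01219, a long noncoding RNA, fell by 2.27 on the log2 scale, from 103 ± 16.2 to 21.4 ± 5.48 CPM (adjusted p = 3.23e-04, edgeR). The unnamed gene BGI_novel_G000330 rose by 2.49 ± 0.46, from 2.33 ± 1.69 to 13.1 ± 1.63 CPM (adjusted p = 0.0402, edgeR). BOLA2B lost its call without shILF2 replicate 1, 2 or 3 (adjusted p = 0.166, 0.171 and 0.103, edgeR), and BGI_novel_G000330 lost its call without those or without scramble replicate 3 (adjusted p = 0.119, 0.171, 0.0850 and 0.0778, edgeR). Summed over both copies, BOLA2 and BOLA2B did not pass the test (-2.95 ± 1.16, adjusted p = 0.316, edgeR). Of the 371 genes called, 105 (28.3%) had a fractional count in at least 1 library, against 38.6% of all genes tested. Among the 23 called with an absolute log2 fold change of at least 2, however, 15 had one. ILF2 had whole counts in 3 libraries and TMEM156 in 4.

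Log2 fold changes also followed the GC content of the genes. Over 13863 genes with a GC value, the Spearman correlation across genes was -0.35, where genes are not independent replicates. Of the 2773 genes with the lowest GC content 50 were called higher and 13 lower, and of the 2773 with the highest 20 were called higher and 118 lower (edgeR, adjusted over the genes with a GC value). Libraries of the same group differed in this trend: the correlation of a library's deviations with GC content was 0.57, 0.39 and -0.42 in scramble replicates 1 to 3 and -0.34, -0.42 and -0.01 in shILF2 replicates 1 to 3. With the trend of each library removed, 747 genes were called, 332 higher and 415 lower, against 528 in the same genes without the correction (194 higher and 334 lower). Of the 371 genes, 351 had a GC value, 345 of these were called after the correction, and 0 of the 351 changed sign.

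**Figure D3:**
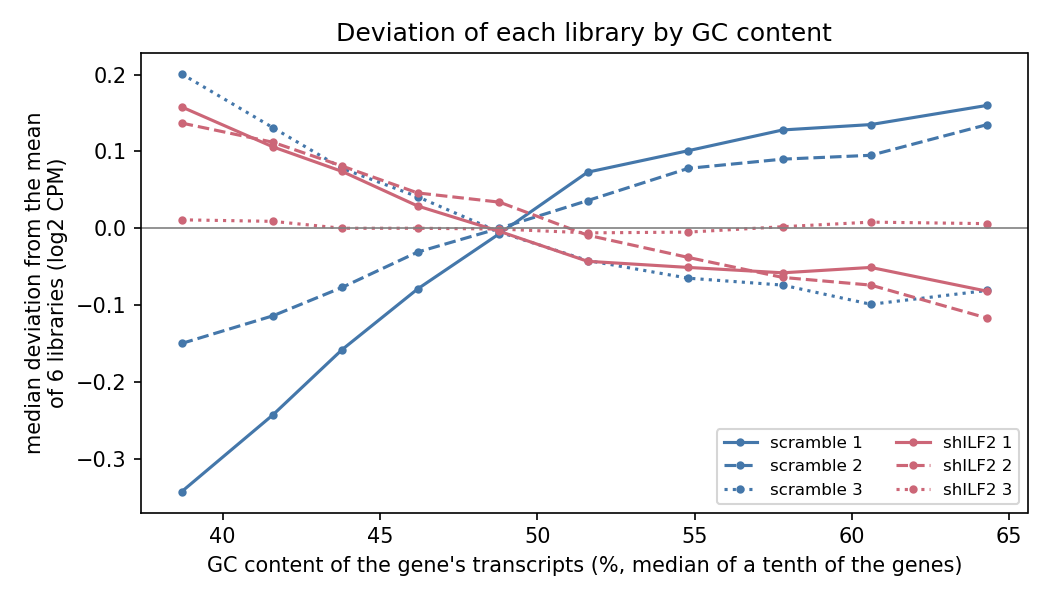
Median deviation of each library from the mean of the 6 libraries (log2 CPM) in 10 groups of genes ordered by GC content (%), with scramble in blue and shILF2 in red. Scramble replicate 3 runs with shILF2 replicates 1 and 2, from 0.20 in the group with the lowest GC content to -0.08 in the highest, while scramble replicate 1 runs from -0.34 to 0.16.

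In the list of E2F targets and DNA replication genes, 3 of 40 members tested fell, 0 rose and 37 did not pass over all genes (edgeR). Camera called the list lower (median -0.32, adjusted p = 1.67e-13), but not with an estimated correlation of 0.47 between members (adjusted p = 0.564, camera). ORC1, a subunit of the origin recognition complex, fell by 0.80 on the log2 scale, from 21.2 ± 2.75 to 12.2 ± 1.58 CPM. E2F2, a transcription factor of the family itself, had a log2 fold change of -0.73 ± 0.15, and GINS4, a component of the replicative helicase, of -0.65 ± 0.15. When adjusted over the list alone 22 were lower, and 39 had a negative fold change. Over the genes with a GC value its median was -0.34 both with the GC trend removed (adjusted p = 2.31e-13) and without (adjusted p = 1.03e-12, camera), and over 17 alternatives the adjusted p ran from 7.56e-17 to 0.564. ORC1, E2F2 and GINS4 each lost their call without scramble replicate 2 (adjusted p = 0.0896, 0.122 and 0.175), without shILF2 replicate 1 (0.0963, 0.0878 and 0.166) and without shILF2 replicate 2 (0.132, 0.171 and 0.174, edgeR). E2F2 and GINS4 also lost it when only total counts were scaled (adjusted p = 0.0558 and 0.0906, edgeR), and the highest adjusted p over 18 alternatives was 0.132 for ORC1, 0.171 for E2F2 and 0.175 for GINS4.

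Of 40 members tested in the list of mitosis genes, 1 fell and 39 did not pass, and 4 were lower when adjusted over the list alone. The member that fell was CCNB1, the cyclin that drives entry into mitosis, at -0.42 ± 0.10 (163 ± 7.94 to 122 ± 3.70 CPM, adjusted p = 0.0483, edgeR). The list's median was -0.16 (adjusted p = 0.00355, camera; adjusted p = 0.539 with an estimated correlation), and over the genes with a GC value it was -0.19 with the GC trend removed and -0.18 without (adjusted p = 7.65e-07 and 0.00729, camera). Camera did not call it without scramble replicate 3, the library that ran with shILF2 replicates 1 and 2 in its GC trend (median -0.11, adjusted p = 0.0693), and CCNB1 lost its call without scramble replicate 2 or any 1 shILF2 replicate (adjusted p from 0.105 to 0.308, edgeR) and when only total counts were scaled (adjusted p = 0.0507, edgeR).

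In the list of p53 targets 2 of 32 members tested rose, 0 fell and 30 did not pass (edgeR). GADD45A, a stress-induced growth arrest gene, rose from 153 ± 33.2 to 244 ± 9.31 CPM (log2 fold change 0.68 ± 0.14, adjusted p = 0.0286, edgeR), and CYFIP2, a regulator of actin assembly, from 63.8 ± 2.95 to 99.6 ± 3.61 CPM (0.64 ± 0.10, adjusted p = 0.00640, edgeR). When adjusted over the list alone 5 were higher and 2 lower. The median was 0.21 and camera called the list higher (adjusted p = 8.84e-04), but not with an estimated correlation of 0.0034 (adjusted p = 0.328, unadjusted p = 0.0122, camera). That estimate lay below the preset 0.01, so a higher correlation between members does not explain the lost call. Over the genes with a GC value the median was 0.24 with the GC trend removed and 0.19 without (adjusted p = 5.91e-05 and 0.00222, camera). GADD45A kept its call only without scramble replicate 1; without scramble replicate 2 or 3 or shILF2 replicate 1, 2 or 3 its adjusted p was 0.105, 0.0604, 0.138, 0.135 and 0.0858, and that of CYFIP2 was 0.0595 without shILF2 replicate 2 (edgeR).

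In the list of inflammatory cytokines and NF-kB targets 2 of 24 members tested rose, 0 fell and 22 did not pass (edgeR). Camera called the list higher (median 0.22, adjusted p = 0.0138), but not with an estimated correlation of -0.0162 (adjusted p = 0.361, unadjusted p = 0.0268, camera). Here too the estimate lay below the preset 0.01, so a higher correlation between members does not explain the lost call. CCL2 rose as given above, and PTGS2, the inducible cyclooxygenase, rose from 37.1 ± 4.23 to 56.1 ± 1.48 CPM (log2 fold change 0.59 ± 0.12, adjusted p = 0.0203, edgeR). When adjusted over the list alone 3 were higher and 1 lower. The list's call was also lost with ranks (adjusted p = 0.0969) and without scramble replicate 3 (adjusted p = 0.0673, camera). With 1 library left out, its median ran from 0.13 without shILF2 replicate 3 to 0.21 without shILF2 replicate 2. Over the genes with a GC value the list's median was 0.23 with the GC trend removed and 0.20 without (adjusted p = 0.0158 and 0.0157, camera), while the gene PTGS2 lost its call with the trend removed (0.40 against 0.58 without, adjusted p = 0.0585 against 0.0168, edgeR; 3.85e-04 to 0.125 over 18 alternatives). PTGS2 also lost it without scramble replicate 2 or shILF2 replicate 1, 2 or 3 (adjusted p = 0.103, 0.125, 0.101 and 0.0812, edgeR).

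**Figure D4:**
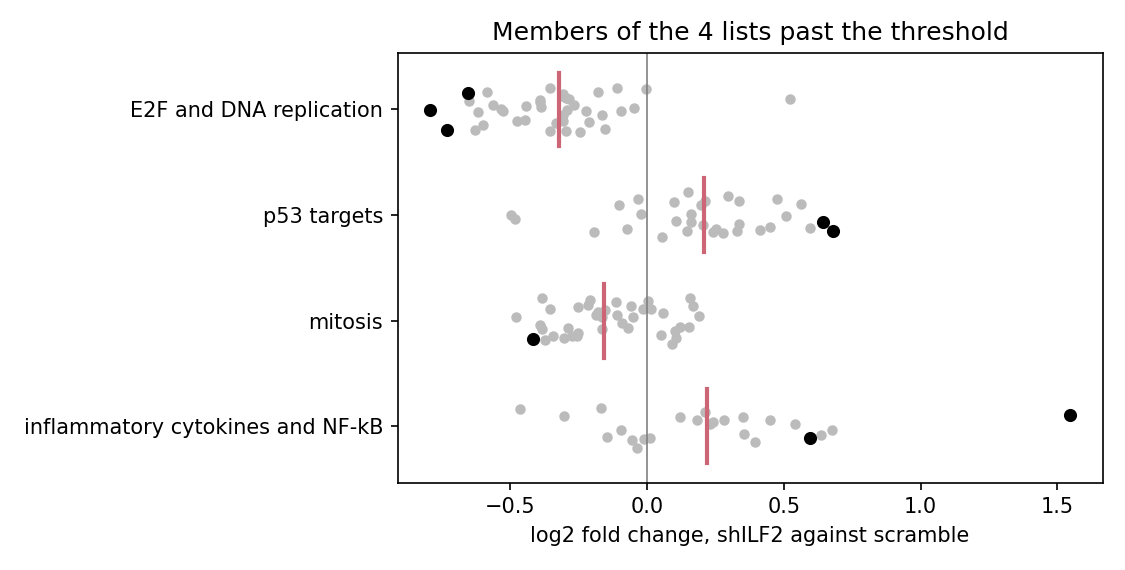
Log2 fold change, shILF2 against scramble, of each tested member of the 4 lists called by camera, with black points for members past the threshold over all genes, grey points for the others, and a red line at the list's median. The medians lie at -0.32, 0.21, -0.16 and 0.22 from top to bottom, and the vertical spread within a list only separates the points.

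With an estimated correlation, camera called 0 of the 27 lists (2 had an unadjusted p under 0.05), and fry called 0 (6 unadjusted) for a shift in 1 direction and 15 for changes in either direction. Splits of the 6 libraries that mixed the groups gave up to 11 lists called by camera with the preset correlation, against 4 for the real groups.

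Of the 23 lists not called, 12 held members past the threshold, in both directions in 4 of them; the genes of these lists given here were named after their values were seen. In the list of glycolysis and hypoxia, ADM, a vasodilator peptide, rose (0.80 ± 0.12) while SLC16A3, a lactate exporter (-1.05 ± 0.12), and ANGPTL4 (-0.81 ± 0.12) fell, and 30 of 33 did not pass. Among epithelial junction and keratin genes, CLDN1, a tight junction claudin, rose (0.91 ± 0.14), TJP3 (-0.93 ± 0.17), CRB3 (-1.13 ± 0.24) and KRT19 (-1.24 ± 0.27) fell, and 24 of 28 did not pass. Immediate early genes were divided, with SPRY2 (0.81 ± 0.13) and FOSL1 (0.80 ± 0.17) higher, NR4A1 (-0.91 ± 0.15) and KLF4 (-0.47 ± 0.10) lower and 19 of 23 not past the test. The apoptosis list had 2 falls, CASP9, an initiator caspase (-0.85 ± 0.15), and BCL2L2 (-0.53 ± 0.11), and 25 of 27 members did not pass. BCL2L2 had no whole expected count in any library, SLC16A3 had whole counts in 1 library, and CRB3 and NR4A1 in 2. At least some of their reads were therefore divided with other genes, and their changes are uncertain in that respect. The share of divided reads was not measured. It need not be as large as for BOLA2B.

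A single member passed in each of 5 further lists. OAS1, an antiviral enzyme, fell (-0.95 ± 0.13) among 31 interferon response genes. ALDH3A1 fell (-0.68 ± 0.13) among 32 NRF2 targets, and EXO1, a DNA exonuclease, fell (-0.58 ± 0.12) among 25 homologous recombination and Fanconi genes. PPP1R15A rose (0.70 ± 0.16) among 32 genes of the unfolded protein response and ATF4, and TGFB2, a secreted growth factor, rose (1.17 ± 0.21) among 32 TGF-beta targets and mesenchymal genes. The camera adjusted p of the lists in these paragraphs ran from 0.0632 for cholesterol synthesis (25 tested) and 0.197 for epithelial genes to 0.849 for NRF2 targets, with 0.256 for the unfolded protein response, 0.281 for glycolysis and hypoxia, 0.368 for homologous recombination, 0.475 for interferon response, 0.4999 for mesenchymal genes and for apoptosis, and 0.740 for immediate early genes. Over the genes with a GC value and with the GC trend removed, camera called cholesterol synthesis (median -0.13, adjusted p = 0.0334, against 0.0802 without the correction) and homologous recombination (median -0.21, adjusted p = 0.0109, against 0.424), though not with an estimated correlation (adjusted p = 0.838 and 0.691). ADM, SLC16A3, ANGPTL4, CLDN1 and OAS1 kept their call without any 1 library, and the other 13 genes named in these paragraphs after their values were seen lost it in at least 1 case. The adjusted p of those that lost it (edgeR) was 0.0693 without scramble replicate 1 (CRB3), 0.0600 to 0.170 without scramble replicate 2 (TJP3, CRB3, KRT19, BCL2L2, KLF4, FOSL1, ALDH3A1 and PPP1R15A), and 0.0889 for FOSL1 and 0.102 for PPP1R15A without scramble replicate 3. It was 0.0628 to 0.234 without shILF2 replicate 1 (TJP3, CRB3, KRT19, CASP9, BCL2L2, SPRY2, KLF4, FOSL1, EXO1, ALDH3A1 and PPP1R15A), 0.0600 to 0.184 without shILF2 replicate 2 (all 13), and 0.0547 to 0.0834 without shILF2 replicate 3 (CRB3, BCL2L2, KLF4, PPP1R15A and TGFB2). KRT19 also lost its call when only total counts were scaled (adjusted p = 0.0627) and PPP1R15A with DESeq2 size factors (adjusted p = 0.0514, edgeR). With 1 library left out, the log2 fold change ran from -0.57 to -0.52 for BCL2L2 and from 0.57 to 0.92 for PPP1R15A. Calls were thus lost with little change in size as well as with more.

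Adjusted over the list alone, 1 higher and 3 lower genes passed in the glycolysis and hypoxia list, 3 and 6 in the epithelial list, 4 and 6 among immediate early genes, 1 and 2 among apoptosis regulators and 3 and 2 among mesenchymal genes. The same count was 0 and 3 for interferon response, 0 and 2 for NRF2 targets, 0 and 1 for homologous recombination and 1 and 0 for the unfolded protein response.

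No member passed in 11 lists, among them the known partners of ILF2 (15 tested), oxidative phosphorylation (52), splicing factors (40), lysosome and autophagy (32), ribosomal proteins (60), ribosome biogenesis (35), replication-dependent histones (16), and mitochondrial dynamics and mitophagy (25). Of the 286 distinct genes in the 11 lists, 20 had an unadjusted p under 0.05, 10 higher and 10 lower (edgeR), and DESeq2 called 5. Adjusted over the list alone, 2 genes of mitochondrial dynamics were higher and 1 lower, and 0 in the other 10 lists. Their camera adjusted p ran from 0.475 to 0.964. A list's median, mean and camera direction differed in sign in 7 lists, those of interferon response, immediate early genes, NRF2 targets, histones, mitochondrial dynamics, and alveolar and fibroblast markers.

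Markers of immune cells, fibroblasts and endothelium did not pass the test. Immune markers had 5 tested members, led by CD68 (38.3 ± 2.43 CPM in scramble, 39.0 ± 0.928 in shILF2), which is also a lysosomal protein, and ITGAM (3.37 ± 0.430 and 3.85 ± 0.262 CPM). Fibroblast markers had 6, led by FBLN1 (120 ± 13.6 and 102 ± 6.86 CPM) and COL1A1 (22.5 ± 6.75 and 25.9 ± 7.81 CPM), and endothelial markers 3, led by EGFL7 (53.5 ± 8.65 and 47.4 ± 1.23 CPM) and ESAM (0.969 ± 0.449 and 1.48 ± 0.399 CPM). For these 3 lists 0 members passed (edgeR) and the camera adjusted p was 0.849, 0.930 and 0.740. Of 8 alveolar and club cell markers, the lineage of the lung epithelium, CAV1 rose from 135 ± 19.97 to 211 ± 11.5 CPM (log2 fold change 0.65 ± 0.12, adjusted p = 0.0162, edgeR), MUC5B, an airway mucin, fell from 165 ± 22.8 to 73.6 ± 1.19 CPM (-1.17 ± 0.12, adjusted p = 4.31e-04, edgeR), and 6 did not pass (adjusted p = 0.893, camera). CAV1 lost its call without shILF2 replicate 1, 2 or 3 (adjusted p = 0.0603, 0.107 and 0.0588, edgeR). Of 9 neuroendocrine markers, SYT1 rose as given above and 8 did not pass (adjusted p = 0.475, camera), among them UCHL1 (1024 ± 133 and 1109 ± 60.2 CPM) and ENO2 (61.2 ± 7.35 and 62.3 ± 4.16 CPM). Adjusted over the list alone, 2 alveolar and club cell markers were higher and 1 lower, and 1 neuroendocrine marker was higher.

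Of 282 genes annotated to the extracellular region part, 14 were among the 148 genes that rose, with 2.68 given by chance (adjusted p = 0.00154, one-sided Fisher's exact test, Benjamini-Hochberg). The 14 genes included CCL2, TGFB2, SHH, a secreted morphogen (1.19 ± 0.20), SPP1, the matrix protein osteopontin (0.73 ± 0.14), and C5, a complement component (1.18 ± 0.19), of which the last 4 were named after their values were seen. Without shILF2 replicate 1, SPP1 and C5 lost their call (adjusted p = 0.0717 and 0.0521, edgeR), without shILF2 replicate 2 SHH, SPP1 and TGFB2 (0.0697, 0.0948 and 0.0853, edgeR), and without shILF2 replicate 3 SPP1 and TGFB2 (0.0519 and 0.0547, edgeR). The terms response to wounding (7 of 63, adjusted p = 0.00334), animal organ morphogenesis (8 of 100, 0.00507), response to estrogen (7 of 77, 0.00530) and positive regulation of endothelial cell migration (5 of 30, 0.00530) were also called by Fisher's exact test. Among genes that fell, 1 term was called, cell communication (8 of 105 genes, adjusted p = 0.0498, Fisher's exact test). In total 9 terms were called, but only 2 without scramble replicate 1 and 0 without scramble replicate 2 or 3 or shILF2 replicate 1, 2 or 3, where Fisher's exact test gave 128, 243, 96, 104 and 138 unadjusted p values under 0.05. From the genes called by DESeq2, 3 terms were called. The background was all 15587 genes tested, of which 13051 carried a term. With only the genes that carried a term as background, 6 terms were called (Fisher's exact test).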

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

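The GC correction and the test of genes with whole counts only were chosen after the data were seen. No named gene or list that was called changed direction under an alternative that gave it a value; the other genes called were compared in direction only where both settings called them. Outside the leave-outs, 761 values of named genes stayed on the same side of the threshold and 60 lost a call; for lists these were 284 and 9, and 4 gained a call. With 1 library left out, 306 values of named genes stayed and 114 lost a call; for lists 153 stayed, 2 lost and 7 gained a call. Of 62 named genes called, 26 kept the call in all 6 leave-outs. Each leave-out also had fewer libraries and so less power, and a lost call alone does not show that 1 library made it.

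DESeq2 called 950 genes (394 higher, 556 lower), 364 of them among the 371, and gave no adjusted p for 1819. Limma on log2(FPKM + 1) with no filter called 95 (34 higher, 61 lower). An absolute log2 fold change of at least 1 left 108 (50 and 58) and an adjusted p under 0.01 left 112 (48 and 64), by construction. The GC correction gave 747 (332 and 415), against 528 in the same genes without it. Leaving out 1 library gave 86 to 1299 genes, 35 to 702 higher and 51 to 597 lower. The extremes were 86 without shILF2 replicate 2, 82 of them shared with the 371, and 1299 without scramble replicate 3, 360 of them shared, where 46% were lower against 60.1% in the full set. Among genes with a GC value that leave-out gave 1663 genes without the GC correction and 600 with it, so its GC trend bears on the rise; for DESeq2 and limma the cause was not tested.

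Against 9 terms called (Fisher's exact test), 5 were called with DESeq2 size factors, 2 with total counts only, 5 with no filter, 3 with DESeq2, 5 with whole counts only, 0 with an absolute log2 fold change of at least 1 (81 unadjusted), 0 with an adjusted p under 0.01 (100 unadjusted), and 0 to 2 with 1 library left out; these are totals, not counts of the same terms, and the cause was not tested. Of the 27 lists, 4 were called by camera with the preset correlation, 0 with an estimated correlation (2 unadjusted) and 0 by fry (6 unadjusted), and 3 to 8 with 1 library left out, 3 without scramble replicate 3 and 8 without scramble replicate 1.

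The replicate number as a replicate block gave 417 genes, 332 of them among the 371, and 4 terms. Deviations of libraries with the same number correlated at 0.068, -0.089 and -0.066, and only those of replicate 1 correlated best with their own number, so the numbers were not taken to pair the libraries. At this depth, the simulated test recovered 44.8% of genes changed 1.5-fold, so a gene that did not pass is not shown to be unchanged.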

Other observations

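The GC correction, with the corrected count without scramble replicate 3, and the matched lists were chosen only after the results were seen. So were the BOLA2 sum, the YAP and TAZ list and the transcript lengths. The leave-outs, the splits and camera with an estimated correlation were planned. Only the use of that correlation to weigh the growth state of the cultures came later. Among the genes with a GC value, 9 of the 40 E2F and DNA replication genes and 4 of the 40 mitosis genes fell and 0 rose with the GC trend of each library removed (edgeR), against 8 and 3 in the same genes without the correction, so the correction itself moved these counts little. In the list of homologous recombination and Fanconi genes 2 of 25 fell with the correction and 1 without, and the median was -0.21 against -0.12. That list also depended on single libraries. Without the correction, its median over all genes tested was -0.24 without shILF2 replicate 3 and 0.04 without scramble replicate 3.

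Across 13863 genes the log2 fold change fell with GC content (Spearman's rho -0.354 across genes, which are not independent replicates). Libraries of the same group differed in this trend by up to 0.99, against a difference of 0.438 between the group means. A GC bias of single libraries predicted that order. A range over 3 libraries is apt to exceed a difference of means whatever the cause, so the comparison does not decide for such a bias. Scramble replicate 3 lay at -0.42, below shILF2 replicates 1 and 3 and far from scramble replicates 1 and 2 (0.57 and 0.39). The tables argue against the trend as the whole cause of the calls, since 91.7% of the genes called before the correction were called in the same direction after it. The rise in genes called without scramble replicate 3 may come from the GC trend of that library, since among genes with a GC value the count there was 1663 without the correction and 600 with it. An effect of the knockdown on transcripts by their GC content cannot be told apart from library bias, with a two-sided exact permutation p of 0.3 where 3 against 3 cannot go below 0.1.

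The E2F and DNA replication list was lower, with 39 of 40 members negative, though camera did not call it with an estimated correlation (adjusted p = 0.564). GC content, length and expression level are argued against, since at most 0.01% of 10000 lists matched on them had a median as low, the smallest share they can give, with medians from -0.15 to 0.13 against -0.32. A single library is argued against too, since the median nearest 0 over the 6 leave-outs was -0.238. A candidate explanation that stays open is that cultures of the groups differed in growth state for a reason other than the knockdown, since the members moved together between libraries and the unadjusted camera p with that correlation was 0.104. An effect of the knockdown on the cell cycle cannot be told apart from it with these 6 libraries.

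BOLA2B had the largest fall among genes called with at least 10 CPM in the higher group, and its expected count equalled that of BOLA2 in 5 of 6 libraries. In shILF2 replicate 2 the counts were 369.35 for BOLA2 and 12.02 for BOLA2B. Reads split differently between the copies could account for part of the fall, since the summed counts had an adjusted p of 0.316 (edgeR, log2 fold change -2.95 ± 1.16), with sums of 1925, 485 and 1360 in scramble and 46, 381 and 51 in shILF2. A real fall of both copies cannot be told apart from it, because the sums varied widely within each group.

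ANKRD1, TGFB2 and GADD45A, which rose, are known targets of the YAP and TAZ co-activators, so a rise of these targets as a group was a hypothesis. The list of 22 targets as a whole was higher by camera (p = 2.09e-04, and 0.0335 with an estimated correlation). Of its members 15 were higher in shILF2, and the list holds the 3 genes that prompted it. The other 19 had a median of 0.15 and a camera p of 0.134 (0.290 with an estimated correlation), and 12 were higher in shILF2, which leaves the hypothesis open.

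A shift in which transcripts of a gene were used was tested from the abundance-weighted transcript length of 7865 genes. Limma found 0 genes past an adjusted p of 0.05, the smallest adjusted p being 0.0511, while 597 had an unadjusted p under 0.05 where chance gives 393. The number of transcript shifts is left open, since length misses shifts between transcripts of like length.

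The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real groups gave 371 genes and the highest other split 1 gene, so 1 of the 10 splits gave as many. For terms the real groups gave 9 and the highest other 0, so again 1 of 10 gave as many. For gene lists 7 of the 10 splits gave at least the 4 lists of the real groups, with up to 11 (camera, preset correlation). What gave the lists in the mixed splits was not tested.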
